A study of Mus musculus with 6 samples.

How the data were processed

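RNA was measured in whole hypothalamus, the brain region that controls feeding, body temperature and pituitary hormone release, from 3 wild-type (WT) and 3 NS-DADm mice of the C57BL/6 strain, aged 3 to 4 months. Each library came from the total RNA of 1 mouse, so the 3 libraries of a group were separate animals. The deposited values were read counts per gene symbol, 1 table per library. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9 to the mm10 mouse genome and counted with HTSeq. The HTSeq version, the gene annotation, the strand setting and the library kit are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. No value was normalized in the deposited count tables.

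Each table held 24518 rows, of which 24513 were genes. The other 5 rows were classes of unassigned reads, and they were kept out of library sizes and tests. Reads outside any gene made up 13.3 to 14.8% of all counted entries, reads that fitted more than 1 gene 1.00 to 1.06%, and alignments that were not unique 14.3 to 16.5%. Because alignments that were not unique were left out of the gene rows, genes with near-identical copies were undercounted. The reads assigned to genes numbered 24.2 M to 27.6 M per library, and 18766 to 18916 genes had at least 1 read. The 10 most abundant genes took 3.03 to 3.49% of these reads.

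Counts were filtered with filterByExpr, scaled with TMM factors (0.992 to 1.01) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust shrinkage and without covariates. The filter left 15894 genes. The p-values were adjusted with the Benjamini-Hochberg (BH) method over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Normalised read counts (CPM, per 1e6 reads) were computed with the TMM-scaled library sizes. Levels are given as mean ± SD over the 3 libraries of a group. The common biological coefficient of variation was 6.45%.

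Gene lists for pathways, cell types and neighbouring tissues, 42 in all, were fixed before the data were examined. Of these, 40 had at least 3 tested members and were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with BH adjustment over the 40 lists. Camera with an estimated correlation and the fry test were run beside it. For each list, members past the threshold were counted over all genes tested and with p-values adjusted over the list alone. The adjustment over the list alone was not corrected for the number of lists. The list of blood cell markers had 2 tested members and the list of mitochondrially encoded genes had 0, so neither was tested with this filter and all 6 libraries.

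The genes named in the text were chosen by a rule fixed before the data were examined. They included Ncor1 and Hdac3, the 12 genes with the largest fitted change in each direction among called genes with a mean of at least 1 CPM and no overlap between the groups' libraries, and, from each list described, up to 4 members with the smallest p and at most 6 where more passed the threshold over the list alone. Some genes that the rule names, and a planned comparison that needs 1 of them, are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

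Gene positions were taken from the GENCODE annotation of the same genome build, and from RefSeq where GENCODE lacked the symbol. A match was found for 24325 of the 24513 symbols (99.2%). The closest other transcript of selected genes was found with BLAST 2.17.0. Figures were drawn with matplotlib 3.10.9.

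The fit was tested on simulated data with counts drawn for the 15894 genes from the real means, library sizes and dispersions, in 12 runs with different random seeds. Changes were given only to genes with a mean above 1 CPM, so recovery at lower levels was not measured. Earlier single runs, 1 with another smallest fold and 1 with the present one, had been seen before these runs were chosen. For the comparison of NS-DADm with WT, the fit recovered 367 of 599 genes changed 1.3-fold over all runs (61.3%, 46 to 70% per run), 484 of 599 changed 1.5-fold (80.8%), 568 of 600 changed 2-fold (94.7%) and 596 of 600 changed 3-fold (99.3%). Of its 2275 calls, 195 were false (8.57%, 4.40 to 12% per run), a larger share than the threshold of 0.05 sets. With no simulated change, a run called 0 to 6 genes, and 1 of the 12 runs called lists, 3 in number. Simulated genes varied independently of each other, unlike the real thalamus marker list, whose estimated correlation was 0.88. The list results of these runs therefore do not cover lists whose genes vary together. A simulated 1.3-fold decrease in a list of 15 genes gave camera adjusted p-values of 5.67e-18 to 1.93e-05, and other lists were then called in 3 of the 12 runs.

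Alternatives fixed before the data were examined were other scaling factors, DESeq2 1.42.0, limma voom, no robust shrinkage, other count filters, the replicate number as a block, other thresholds, a minimum fold and leaving out each library. An additive covariate for thalamus markers, and leaving out WT 1 and NS-DADm 2 together, were added after the data had been seen. All 6 libraries were analysed.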

Results

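Hypothalamic RNA from 3 WT and 3 NS-DADm mice was compared by sequencing. NS-DADm mice, as known for this mouse line rather than from the labels, carry mutations in the deacetylase-activating domain of nuclear receptor corepressors including NCOR1, which bind and activate the histone deacetylase HDAC3. The comparison addresses how hypothalamic transcript levels differ when this domain is mutated. The libraries held 27.4 M, 27.6 M and 26.5 M reads (in units of 1e6) on genes in WT 1, 2 and 3, and 24.2 M, 27.5 M and 26.4 M in NS-DADm 1, 2 and 3. Within each group, pairs of libraries differed by 3.30 to 9.98 times the counting noise in a chi-square test per degree of freedom, so no pair within a group agreed within that noise; pairs across groups were not compared.

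Neither Ncor1 nor Hdac3 passed the threshold. Ncor1 (chromosome 11, 62316426 to 62458541, minus strand) measured 230 ± 7.4 CPM in WT and 226 ± 3.9 CPM in NS-DADm mice (mean ± SD, n = 3 each; edgeR, BH adjusted p = 0.91). Hdac3 (chromosome 18, 37935844 to 37955016) measured 99.6 ± 2.6 and 107 ± 0.63 CPM (edgeR, BH adjusted p = 0.43). None of the 6 tested members of the NCOR-HDAC3 complex passed the threshold, over all genes or adjusted over the list alone; Tbl1xr1 had a log2 fold change of -0.12 and Tbl1x of 0.06, both short of it. A small change in coding sequence need not alter a transcript's level, so these values do not check the genotype labels. All 6 libraries had reads on Y-linked genes, with 2923 to 3590 counts of Ddx3y, and 6 to 17 counts of Xist, the RNA that silences an X chromosome in females.

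Between NS-DADm and WT hypothalamus, 104 of 15894 genes passed the threshold, 13 higher and 91 lower in NS-DADm mice. In all 104 the 3 libraries of one group lay on one side of the 3 of the other, as they did in 16.8% of all tested genes, against 10% by chance. Without an adjustment, 1726 genes had a p under 0.05, 699 higher and 1027 lower. The median log2 fold change over tested genes was 0.004. The number of calls depended on single libraries, since it was 312 without WT 1, 262 without WT 2, 10 without WT 3, 5 without NS-DADm 2 and 8 without NS-DADm 3. It was also 282 with the DESeq2 Wald test, 203 with no count filter and 8 against a minimum fold of 1.2, while all 104 kept their direction in each of these fits.

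Among the 13 genes called higher in NS-DADm mice, the largest fitted increases were those of Gpr84, Plin4 and Adam8. Gpr84, a receptor for medium-chain fatty acids found on myeloid cells, rose 2.50-fold from 0.58 ± 0.091 to 1.45 ± 0.10 CPM (log2 fold change 1.32 ± 0.23 SE; edgeR, BH adjusted p = 0.026), a level that rested on 13 to 17 counts in WT and 33 to 43 in NS-DADm libraries. Plin4, which coats lipid droplets (chromosome 17, 56100591 to 56109803), rose 2.03-fold from 4.80 ± 0.33 to 9.77 ± 1.1 CPM (log2 1.02 ± 0.12 SE; edgeR, BH adjusted p = 0.0028). The complement gene C4b rose 1.57-fold, from 24.5 ± 1.8 to 38.3 ± 3.1 CPM (edgeR, BH adjusted p = 0.0033), and Mpeg1, a pore-forming protein of macrophages, rose 1.29-fold. Adam8, a metalloprotease of leukocytes, and Slc1a5, a glutamine transporter, rose 1.89-fold and 1.75-fold. Blood cell markers had few counts. S100a9, of neutrophils, had 8, 2 and 9 counts in WT 1, 2 and 3 and 11, 19 and 22 in NS-DADm 1, 2 and 3. Alas2 did not rise, with 30, 21 and 30 counts in WT 1, 2 and 3 and 19, 29 and 30 in NS-DADm 1, 2 and 3. Both genes were chosen after their values were seen. The blood cell list had 2 tested members, 1 fitted above 0 and 1 below, and was too short to test. Where at least 3 members were tested it was called higher with no count filter (camera, BH adjusted p = 1.87e-05) and without WT 1, WT 3 or NS-DADm 1 (0.018, 0.0040 and 0.00046), and not without WT 2 (0.096). These calls therefore do not show a rise shared by all blood cell markers.

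Nnt, a mitochondrial transhydrogenase, rose 1.75-fold from 23.6 ± 5.2 to 41.4 ± 1.2 CPM (edgeR, BH adjusted p = 0.039). Ryr2, an intracellular calcium release channel, rose 1.25-fold from 174 ± 12 to 217 ± 7.6 CPM, and Smad3, which carries TGF-beta signals, 1.26-fold. Sfrp5, a secreted WNT inhibitor, and the tubulin ligase gene Ttll3 each rose by a log2 fold change of 0.38, and Sfi1, a centrosome protein, rose 1.25-fold. The remaining gene was Trh. C4b and Sfi1 are uncertain, because C4b shares 96.0% identity over 5378 bases with C4a and Sfi1 shares 94.1% over 1369 bases with Gm2420. Plin4 alone of the higher genes named under the size rule was past the threshold with each other set of scaling factors, DESeq2, limma voom, a minimum of 1 CPM and each library left out. It was not with the mean of the thalamus markers as a covariate (log2 0.80; edgeR, BH adjusted p = 0.35). With WT 3, NS-DADm 2 or NS-DADm 3 left out, 2, 1 and 2 genes in all were called higher, and 102 and 36 were without WT 1 or NS-DADm 1. Anterior pituitary hormone genes were also at their highest in NS-DADm 2, as given with that list.

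**Figure D1:**
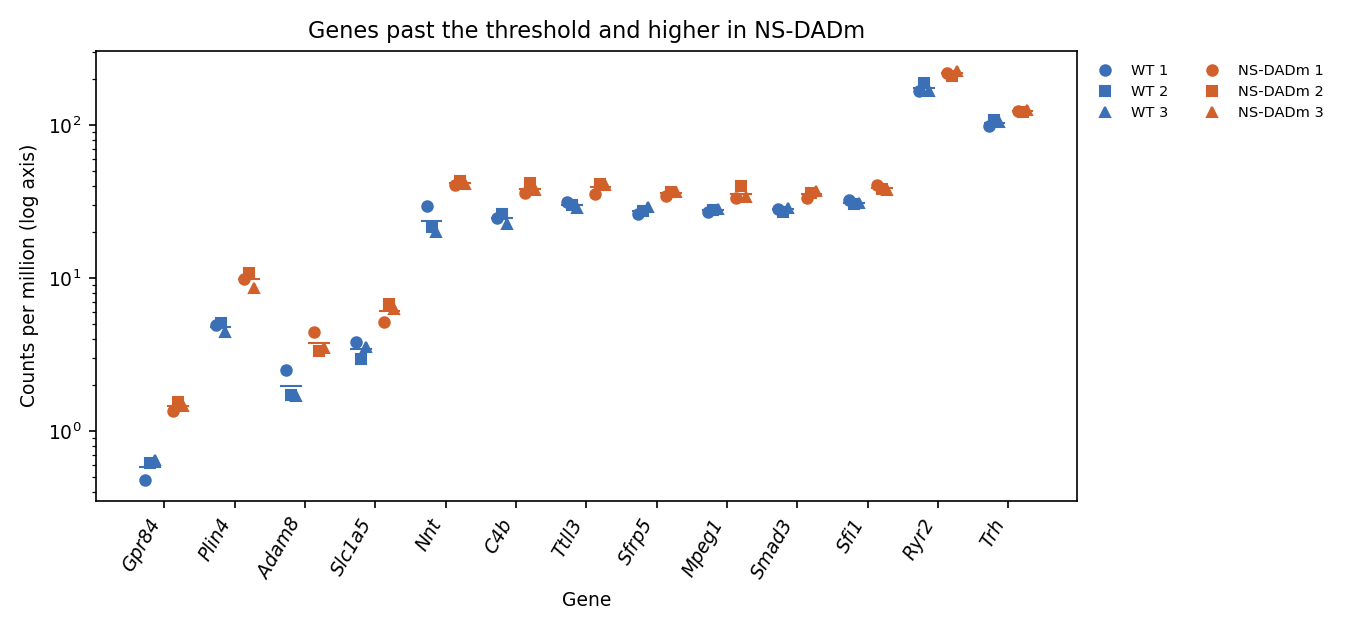
CPM (log axis) of the 13 genes past the threshold and higher in NS-DADm mice. Each point is 1 library, with a symbol for each replicate number and a colour for each group, and each short line is the mean of 3 libraries. For each gene the 3 NS-DADm libraries lie above the 3 WT libraries.

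Lower transcripts in NS-DADm mice were led by Abhd12b, a predicted hydrolase (chromosome 12, 70154142 to 70183887), which fell from 4.36 ± 2.3 to 0.22 ± 0.14 CPM (log2 -4.30 ± 0.61 SE; edgeR, BH adjusted p = 0.043). Its fold is imprecise, since the NS-DADm libraries held only 2 to 9 counts against 69 to 189 in WT. Gm15446, a predicted zinc-finger gene (chromosome 5, 109923400 to 109943936), fell 4.50-fold from 6.26 ± 1.2 to 1.38 ± 0.31 CPM (log2 -2.17 ± 0.20 SE; edgeR, BH adjusted p = 0.00082). It is uncertain because it shares 97.4% identity over 1765 bases with its neighbour Zfp932, which was chosen after its values were seen and fell from 58.0 ± 5.3 to 35.3 ± 0.80 CPM (edgeR, BH adjusted p = 0.00082). Log2 fold changes were -1.45 for the proton-sensing receptor gene Gpr4, -1.39 for the magnesium channel gene Trpm6, -1.33 for the WNT ligand gene Wnt9b and -1.30 for Mctp2. They were -1.25 for Gpat2 and Rab37, -1.17 for Vav3 and -1.15 for the heparin cofactor gene Serpind1. Gm15446 alone of these was past the threshold in each of the fits named for Plin4. It was not with the covariate (log2 -1.76, edgeR, BH adjusted p = 0.17). Log2 fold changes with the covariate were -2.03 for Abhd12b, -0.36 for Gpr4, -0.58 for Trpm6, -0.37 for Wnt9b and -0.70 for Mctp2. Those of Gpat2, Rab37, Vav3 and Serpind1 were -1.14, -0.11, -0.20 and -0.17. None of these genes was past the threshold in that fit. Counts of lower genes were 8, 4 and 6 without WT 3, NS-DADm 2 or NS-DADm 3, and 210 and 243 without WT 1 or WT 2. Markers of thalamus, the region next to hypothalamus, were lower in the same libraries.

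All 15 thalamus markers had lower values in NS-DADm mice, 5 of them past the threshold over all genes and 15 adjusted over the list alone. The list had a median log2 fold change of -1.21 (camera, BH adjusted p = 1.45e-45; adjusted p = 0.18 with an estimated correlation). Lef1, a WNT-pathway transcription factor, fell 2.18-fold from 16.7 ± 3.0 to 7.67 ± 0.34 CPM, and Plekhg1 fell from 73.2 ± 14 to 32.6 ± 3.5 CPM (edgeR, BH adjusted p = 0.0028 and 0.031). Rgs16, a regulator of G-protein signalling, had a log2 fold change of -0.81, Slitrk6 of -0.71 and Plcb4 of -0.25. Ntng1 passed the threshold over the list alone with a log2 fold change of -0.91. The mean log2 CPM of the 15 markers was 5.96, 5.10 and 5.59 in WT 1, 2 and 3, and 4.48, 4.08 and 4.43 in NS-DADm 1, 2 and 3, so WT libraries also differed among themselves. With this mean as a covariate, an alternative added after the data had been seen, 12 genes passed the threshold, 8 higher and 4 lower, and 1 of the 104 calls was kept.

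**Figure D2:**
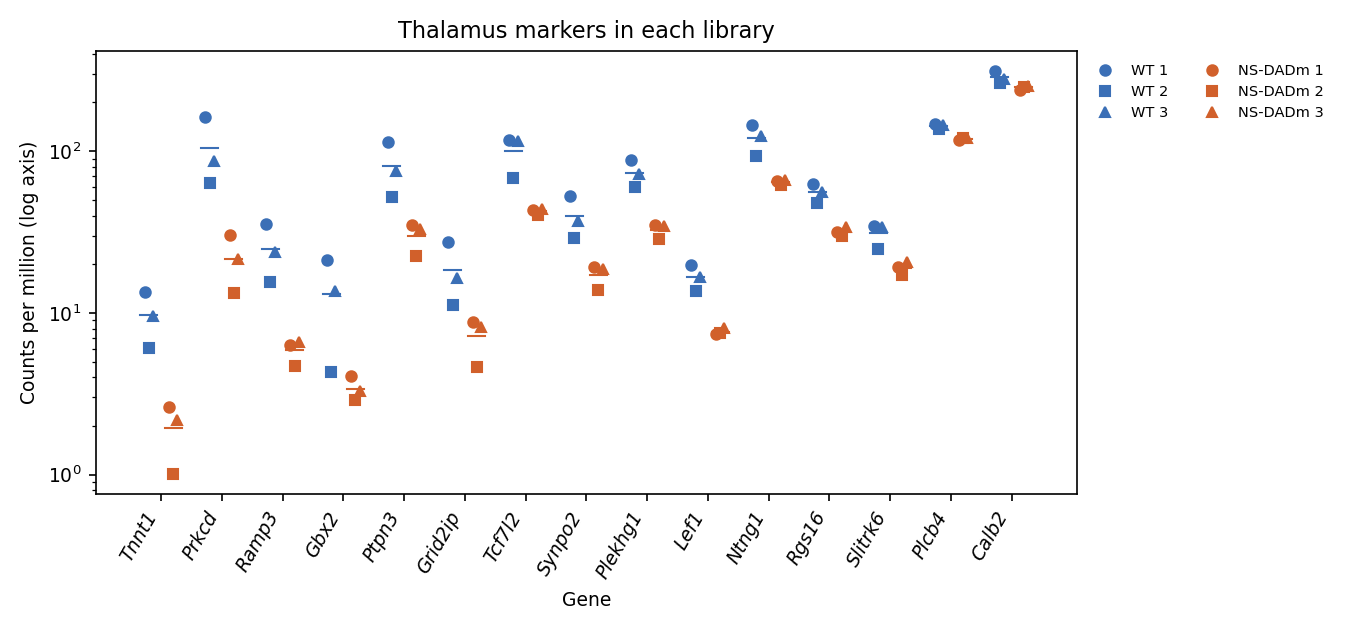
CPM (log axis) of the 15 thalamus markers, with 1 point per library, a symbol for each replicate number and a short line at the mean of 3 libraries. Markers run from the lowest log2 fold change at the left to the one nearest 0 at the right, and WT 1 lies above WT 2 for each of them.

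Genes induced by glucocorticoids were on balance higher in NS-DADm mice. Of 18 tested members, 1 rose past the threshold over all genes and 3 adjusted over the list alone, none fell, and the list's median log2 fold change was 0.12 (camera, BH adjusted p = 4.34e-06; adjusted p = 0.18 with an estimated correlation). The 3 were Plin4, the cell cycle inhibitor gene Cdkn1a (log2 0.41 ± 0.10 SE, 5.34 ± 0.23 to 7.11 ± 0.22 CPM) and the transcription factor gene Zbtb16 (log2 0.51 ± 0.15 SE). Hif3a had a log2 fold change of 0.72 ± 0.22 SE and was not past the threshold. With the thalamus marker covariate the list lost its call at a median log2 of 0.08 (camera, BH adjusted p = 0.55).

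Circadian clock genes were lower in part. Of 20 tested members, 2 fell past the threshold over all genes, and adjusted over the list alone 6 fell and 1 rose (median log2 -0.06; camera, BH adjusted p = 9.12e-05; adjusted p = 0.18 with an estimated correlation). Rora, a nuclear receptor that activates Arntl, fell from 174 ± 26 to 97.8 ± 9.0 CPM (edgeR, BH adjusted p = 0.031), and Hlf, a clock output transcription factor, from 152 ± 8.0 to 119 ± 1.7 CPM (edgeR, BH adjusted p = 0.0087). Bhlhe40, Rorb, Npas2 and Arntl fell over the list alone, with log2 fold changes of -0.27, -0.30, -0.38 and -0.21. The thalamus markers were lower in the same libraries, and with their covariate the list lost its call at a median log2 of -0.09 (camera, BH adjusted p = 0.20). In that fit Rora and Hlf had log2 fold changes of -0.20 and -0.21, against -0.83 and -0.36 without it, and neither passed the threshold. Bhlhe40, Rorb and Arntl had -0.25, -0.33 and -0.12 there, and Npas2 had 0.03.

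Receptor genes for GABA and glutamate, the main inhibitory and excitatory transmitters, included lower members. Of 18 GABA receptor genes, 1 fell over all genes, and adjusted over the list alone 4 fell and 1 rose (median log2 -0.01; camera, BH adjusted p = 0.038; adjusted p = 0.52 with an estimated correlation). Gabra4 fell from 84.5 ± 13 to 50.5 ± 2.6 CPM (edgeR, BH adjusted p = 0.024), and Gabbr1, Gabrb2 and Gabbr2 fell over the list alone with log2 fold changes of -0.22, -0.20 and -0.21, whereas Gabrr2 rose with 0.74. Among 28 glutamate receptor and transporter genes, 0 passed the threshold over all genes and 4 fell adjusted over the list alone (median log2 -0.03; camera, BH adjusted p = 0.018; adjusted p = 0.33 with an estimated correlation). Among these were Slc17a6, the vesicular glutamate transporter of subcortical neurons (log2 -0.23 ± 0.05 SE), Grm4 (-0.44) and Grin2c (-0.42). Without WT 3, WT 2 or NS-DADm 1 the GABA receptor list was not past the threshold (camera, BH adjusted p = 0.51, 0.055 and 0.071), and its median was then 0.02, 0.01 and 0.03. It was past the threshold with a median of -0.06 without WT 1 (camera, BH adjusted p = 1.33e-06), and with -0.01 and -0.03 without NS-DADm 2 and 3. The glutamate list's median was -0.02 without NS-DADm 3. With the thalamus marker covariate the GABA receptor list stayed past the threshold at a median log2 of -0.13 (camera, BH adjusted p = 0.011). Its lower members Gabra4, Gabbr1 and Gabrb2 then had log2 fold changes of only -0.14, -0.08 and -0.03, none past the threshold, and Gabrr2 had 0.77. The glutamate list was not past the threshold at a median log2 of -0.03 (camera, BH adjusted p = 0.79), with Slc17a6 at -0.25. Gabbr2, Grm4 and Grin2c had fitted values above 0 with the covariate.

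Hypothalamic neuropeptide genes were on balance higher in NS-DADm mice, with 1 of 35 past the threshold over all genes and 5 higher and 0 lower adjusted over the list alone (median log2 0.14; camera, BH adjusted p = 0.0034; adjusted p = 0.44 with an estimated correlation). Trh, which encodes thyrotropin-releasing hormone, rose from 104 ± 5.3 to 124 ± 1.4 CPM (log2 0.26 ± 0.05 SE; edgeR, BH adjusted p = 0.042). Over the list alone, Qrfp and Npy, both encoding peptides that promote feeding, rose with log2 fold changes of 0.75 and 0.40, Ghrh, for growth hormone-releasing hormone, with 0.57, and Nts, for neurotensin, with 0.22. The groups overlapped for Npy, with 11.7 CPM in NS-DADm 3 and 11.8 CPM in WT 2. The list lost its call without WT 1 (camera, BH adjusted p = 0.18) and without WT 1 and NS-DADm 2 together (0.79), and its median was 0.09 without NS-DADm 3. With the thalamus marker covariate the list lost its call and turned direction (median log2 -0.14; camera, BH adjusted p = 0.068), and Npy had a log2 fold change of -0.14.

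Transcripts of myelin-forming mature oligodendrocytes were mostly lower. Of 17 markers, 1 fell over all genes, and adjusted over the list alone 8 fell and 2 rose (median log2 -0.19; camera, BH adjusted p = 1.19e-06; adjusted p = 0.44 with an estimated correlation). Ugt8a, which makes the myelin lipid galactosylceramide, fell from 73.8 ± 6.8 to 51.6 ± 3.7 CPM (log2 -0.52 ± 0.07 SE; edgeR, BH adjusted p = 0.0090). Cldn11 (-0.26), Klk6 (-0.81), Aspa (-0.28) and Mag (-0.22) fell over the list alone. Of 24 cholesterol synthesis genes, 1 fell adjusted over the list alone, Msmo1 (log2 -0.24 ± 0.06 SE), and 0 passed over all genes (median log2 -0.09; camera, BH adjusted p = 1.61e-05; adjusted p = 0.45 with an estimated correlation). Hmgcs1 (-0.17), Dhcr7 (-0.19) and Fdft1 (-0.13) had negative log2 fold changes that did not pass. With the thalamus marker covariate the oligodendrocyte list stayed past the threshold with the preset correlation (median log2 -0.20; camera, BH adjusted p = 6.87e-05; p = 0.17 before adjustment with an estimated correlation), whereas the cholesterol list lost its call and turned direction (median log2 0.04; camera, BH adjusted p = 0.40). The cholesterol list also lost its call without WT 1 and NS-DADm 2 together (median log2 -0.05; camera, BH adjusted p = 0.068), and its median was -0.06 without NS-DADm 2.

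Anterior pituitary hormone genes differed widely between libraries. None of the 10 tested markers passed the threshold, over all genes or over the list alone, although the list's median log2 fold change was 1.55 (camera, BH adjusted p = 0.00056; adjusted p = 0.47 with an estimated correlation). This median was 0.40 without NS-DADm 2 and 2.47 without NS-DADm 3, both past the threshold. With the thalamus marker covariate it was -0.62, and the list was not past the threshold (camera, BH adjusted p = 0.55). Gh, for growth hormone, measured 30.5, 40.6 and 96.0 CPM in WT 1, 2 and 3, and 167, 1810 and 172 CPM in NS-DADm 1, 2 and 3. Prl, for prolactin, measured 172 CPM in NS-DADm 2 and 21.8 and 23.2 CPM in NS-DADm 1 and 3, against 5.63 to 11.0 CPM in WT. Cga and Lhx3 had log2 fold changes of 2.73 and 1.12. Some of the other listed markers, chosen after their values were seen, also had their highest counts in NS-DADm 2. Pou1f1 had 47 there and at most 5 elsewhere, Ghrhr 61 and at most 8, and Lhb 100 and at most 17. Tbx19 did not stand apart, with 39 in NS-DADm 2 and 40 in WT 2. These counts go with some pituitary tissue taken along in NS-DADm 2, but they do not prove it. Whether other libraries held any is not shown, so these values need not be hypothalamic expression alone. Of 20 immediate early genes, 0 passed over all genes and 2 fell adjusted over the list alone, Ier2 (log2 -0.58) and Nptx2 (-0.25), while Jun (-0.25) and Dusp1 (-0.30) did not pass (median log2 -0.19; camera, BH adjusted p = 0.018; adjusted p = 0.63 with an estimated correlation). The immediate early list lost its call without WT 2, WT 3 or NS-DADm 2 (camera, BH adjusted p = 0.0501, 0.25 and 0.39), at medians of -0.19, -0.05 and -0.07. It also lost its call with the thalamus marker covariate at a median of -0.18 (camera, BH adjusted p = 0.85), and without NS-DADm 1 it was past the threshold at -0.30.

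Over all 40 tested lists, 23 passed the threshold with the preset correlation, 8 higher and 15 lower. With an estimated correlation 0 passed, the smallest adjusted p being 0.18, and with fry 1 passed, that of circadian clock genes (adjusted p = 0.049). The median, mean and test differed in sign for nuclear receptors, retinoic acid response genes and heat shock genes, none of which passed. Left out together, WT 1 and NS-DADm 2, the libraries with the highest thalamus and pituitary marker levels in their groups, gave 584 genes past the threshold, 239 higher and 345 lower, and 12 lists.

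**Figure D3:**
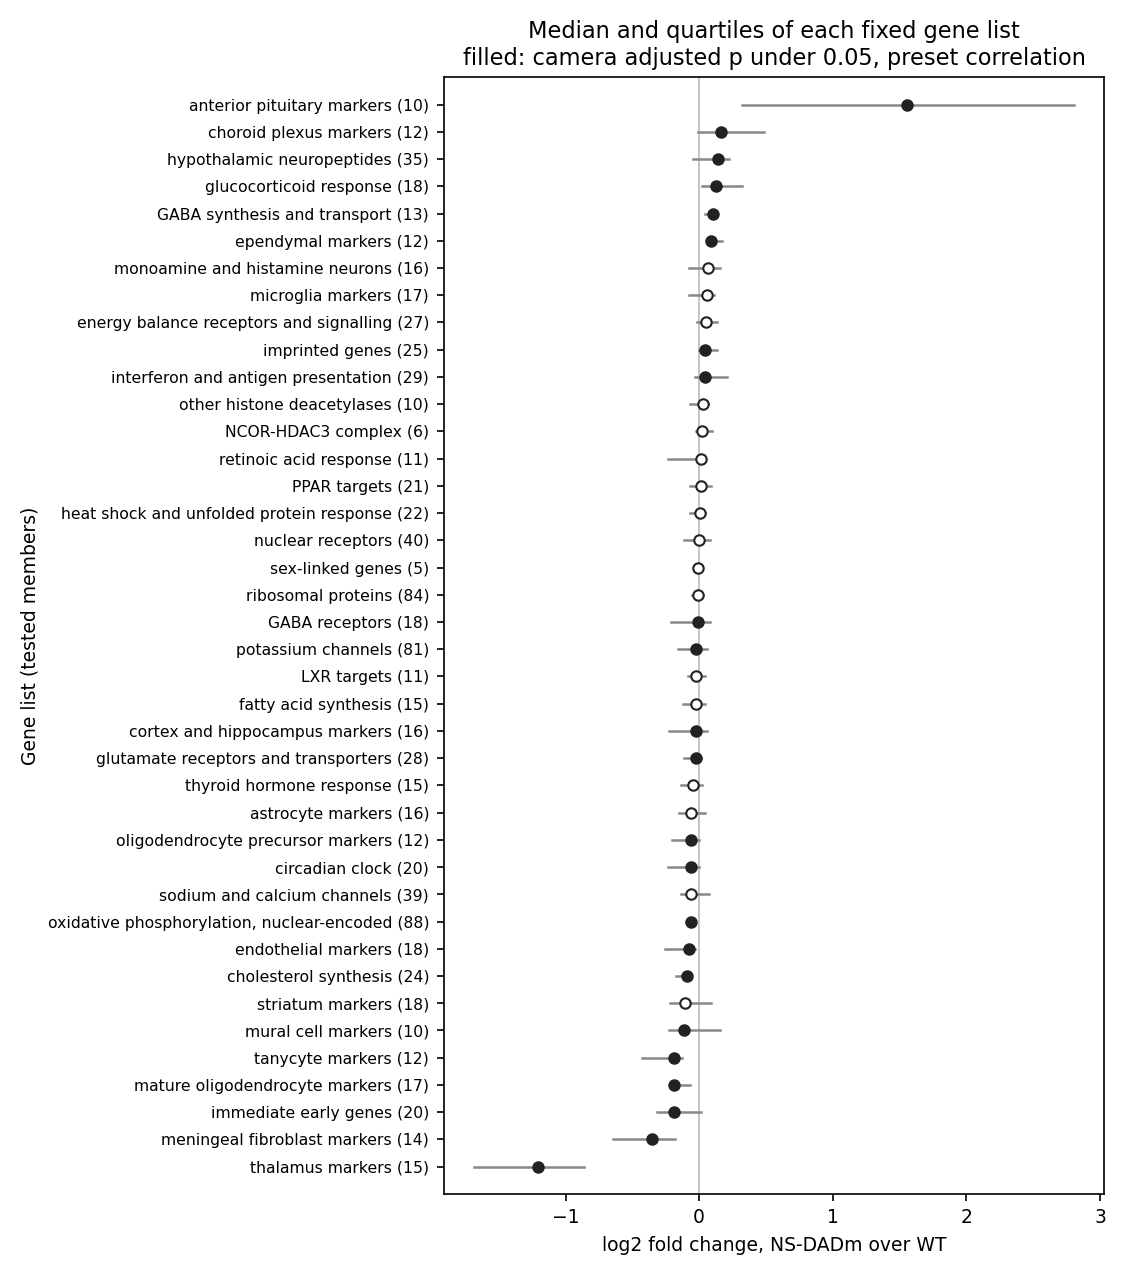
Median (point) and quartiles (line) of the log2 fold change, NS-DADm over WT, over the tested members of each of 40 gene lists, whose number is in brackets. Filled points mark the 23 lists past the threshold with the preset correlation; the thalamus list has the lowest median, -1.21, and the pituitary list the highest, 1.55, which was 0.40 without NS-DADm 2.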

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

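The thalamus marker covariate and the fit without WT 1 and NS-DADm 2 were added after the data had been seen, and the other alternatives were planned. The 104 calls of the edgeR test numbered 104 with DESeq2 size factors, 101 with upper-quartile factors, 72 with library totals only, 86 with limma voom, 117 without robust shrinkage and 90 with a minimum of 1 CPM. All 104 kept their direction in the settings fixed beforehand that tested them, of which the 1 CPM minimum tested 102, and 99 did with the covariate. No scaling moved the median over all genes by over 0.1. Counts of genes past the threshold, higher and lower, moved from 104, 13 and 91 to 282, 50 and 232 with the DESeq2 Wald test, which kept 102 of the 104, to 203, 31 and 172 with no filter, which kept 96, and to 8, 2 and 6 against a fold of 1.2. They were 211, 40 and 171 at a BH threshold of 0.10 and 19, 2 and 17 at 0.01. Library totals gave 60 lower genes. With 1 library left out, they ranged from 5 to 312 in all, from 1 to 102 higher and from 4 to 243 lower. The fits without WT 3, NS-DADm 2 and NS-DADm 3 kept 9, 5 and 8 of the 104, and those without WT 1, WT 2 and NS-DADm 1 kept 100, 96 and 53. The share of lower genes among calls was 87.5%, against 67.3% without WT 1 and 66.0% without NS-DADm 1. Without WT 1 and NS-DADm 2 the counts were 584, 239 and 345, with 95 of the 104 kept, and with the covariate 12, 8 and 4, with 1 kept. Thresholds and filters act by construction. Fits that left libraries out had fewer samples, yet the counts rose in some of them, and the cause of these moves was not tested.

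The 23 lists past the threshold became 15 to 20 with 1 library left out, 12 with the covariate, 12 without WT 1 and NS-DADm 2, 0 with an estimated correlation and 1 with fry.

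With a replicate block for the shared label numbers, 409 genes passed, 77 higher and 332 lower, all 104 calls were kept, and 18 lists passed. Of the 23, those that did not pass there were immediate early genes (adjusted p = 0.059), interferon and antigen presentation (0.067), oligodendrocyte precursor (0.075), mural cell (0.13) and choroid plexus markers (0.051). Whether the numbers pair the samples was not settled. Correlations of deviations from the group means were 0.13, 0.09 and -0.03 for numbers 1, 2 and 3, and -0.12 to 0.06 between different numbers. As a hint from the data and not the design, 4 of the 6 samples correlated best with their own number. These were numbers 1 and 2 in each group, so each such correlation was counted from both sides. Deviations from a mean of 3 libraries also depend on each other, so the count is weak evidence of pairing.

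For the 84 named genes, 1008 of 1258 values kept their direction and side of the threshold, 157 lost the threshold, 77 passed it and 16 changed sign. Each change of sign came with the thalamus marker covariate, whose high correlation with the group widens errors; the cause was not tested further. The log2 fold changes were then -0.91 for Gh, -1.63 for Prl, -0.19 for Cga, -0.33 for Lhx3, -0.14 for Npy, -0.046 for Nnat, -0.058 for Magel2, -0.024 for Itgam, -0.11 for Peg10 and -0.17 for Tbl1x. They were 0.14 for Gabbr2, 0.22 for Jun, 0.029 for Npas2, 0.22 for Grin2c, 0.12 for Grm4 and 0.28 for Cacna2d4. Depth limits genes such as Abhd12b and Gpr84, with counts of 2 to 9 and 13 to 17 in one group. In simulated counts for NS-DADm against WT over 15894 genes, changes were given only to genes with a mean above 1 CPM. Of their 1.3-fold changes 61.3% were recovered, and 8.57% of calls were false. Recovery at lower levels was not measured.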

Other observations

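Sodium and calcium channel genes moved in both directions. Of 39 tested, 4 rose and 5 fell adjusted over the list alone and 0 passed over all genes (median log2 -0.06; camera, BH adjusted p = 0.51). The median moved with single libraries, to -0.0024 without WT 1, -0.0093 without WT 2 and 0.0052 without NS-DADm 2, and it was 0.00081 with no count filter and 0.12 with the thalamus marker covariate. Cacna1e and Cacna1i, which encode pore-forming subunits, rose with log2 fold changes of 0.30 and 0.16, and the auxiliary subunit genes Cacna2d3, Cacng5 and Cacna2d4 fell with -0.24, -0.29 and -0.53. Microglia markers were split as well, with 1 of 17 higher and 1 lower over the list alone (median log2 0.06; camera, BH adjusted p = 0.86), a median that was -0.01 without WT 2, 0.0057 without NS-DADm 2 and -0.02 with the covariate. Ctss, a lysosomal protease, rose with 0.21 and Csf1r, the receptor that keeps microglia alive, fell with -0.26, while Itgam (0.18) and Cx3cr1 (-0.16) did not pass.

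Imprinted genes, expressed from 1 parental copy, had a median log2 fold change of 0.05 with 0 of 25 past the threshold over all genes or over the list alone (camera, BH adjusted p = 0.018; adjusted p = 0.50 with an estimated correlation). Nnat (0.35), Magel2 (0.22), Meg3 (0.14) and Peg10 (0.13) had the smallest p. The list was not past the threshold without WT 1 (camera, BH adjusted p = 0.71) or without WT 1 and NS-DADm 2 together (0.85), and its median was 0.03 without WT 1, 0.08 without WT 2, 0.09 without WT 3 and 0.08 without NS-DADm 2. With the thalamus marker covariate it passed in the opposite direction (median log2 -0.11; camera, BH adjusted p = 0.032). Nuclear-encoded oxidative phosphorylation genes had 0 of 88 past the threshold, with 74 fitted below 0 (median log2 -0.06; camera, BH adjusted p = 1.61e-05; adjusted p = 0.50 with an estimated correlation). Their median was -0.03 without WT 1 and -0.10 without WT 2, and with the covariate the list lost its call and turned direction (median log2 0.04; camera, BH adjusted p = 0.32). Tanycyte markers, of the cells that line the third ventricle, fell in 5 of 12 cases over the list alone and 0 over all genes (median log2 -0.18; camera, BH adjusted p = 0.00084; adjusted p = 0.44 with an estimated correlation). The tanycyte list was not past the threshold without WT 1 and NS-DADm 2 together (camera, BH adjusted p = 0.068) or with the covariate, where it turned direction (median log2 0.02; camera, BH adjusted p = 0.93), and its median was -0.38 without NS-DADm 1.

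In what follows, the tests of tissue share, including the values per library, of oligodendrocyte spread and of shared reads were chosen after the results were seen. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 104 genes and the highest of the other splits 3, with 1 split, the real one, giving as many; for lists the real split gave 23 and the highest other 20, again with 1 giving as many.

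The lower thalamus markers and the 91 lower genes may reflect in part a smaller share of thalamic tissue in the NS-DADm dissections. Of 86 lower genes outside the thalamus list, 87.2% (exact binomial 95% interval 78.3 to 93.4%) were higher in WT 1 than in WT 2. These libraries had the highest and the lowest thalamus score in WT. Of genes not called, 50.2% were higher in WT 1, and the explanation needs such a contrast. The interval treats genes that vary together as independent. It compares 1 mouse with 1 other, so it does not measure the spread between animals. With the score as a covariate the median log2 fold change of the 91 went from -0.49 (quartiles -0.76 to -0.35) to -0.20 (-0.41 to -0.11) and most calls ended, in part because the median SE grew from 0.075 to 0.15, while the mean log2 CPM of the 86 per library still differed between groups by -0.31 ± 0.03 SE, against -0.66 ± 0.08 without the score, so the score did not take up all of their difference. For the 13 higher genes the median went from 0.38 to 0.40 (quartiles 0.27 to 0.83) and all 13 kept their sign. Mpeg1 and Trh shrank, from 0.37 and 0.26 to 0.15 and 0.11, while Adam8 and Nnt grew, from 0.92 and 0.81 to 1.73 and 1.25. The group difference of the 13 genes' mean log2 CPM per library was 0.60 ± 0.09 SE with the score. Their calls ended too as the median SE grew from 0.074 to 0.17. The 86 and the 13 genes were chosen by their group difference in these same libraries. What remains with the score therefore cannot decide whether thalamic share was their whole cause. An effect of the genotype on these genes, or on thalamic tissue itself, stays open and untested, because the score correlated with the group at -0.91 over the 6 libraries.

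Mature oligodendrocyte markers were lower in NS-DADm mice, from 8 of 17 past the threshold over the list alone. Their log2 fold changes differed by more than their SE (Cochran Q, a chi-square test over 17 genes, p = 2.95e-15). Mobp and Mal, chosen after their values were seen, were higher, and Mbp was at -0.09 ± 0.07 SE. The test takes genes as independent, and fewer oligodendrocytes need not lower all markers equally, so this spread cannot decide on fewer cells as the cause. The 2 markers that rose over the list alone are not what fewer such cells alone would give. With the thalamus score as a covariate the list stayed past the camera threshold with the preset correlation (BH adjusted p = 6.87e-05), though not with an estimated one (p = 0.17 before adjustment, against 0.11 without the score), and its median was -0.20 (bootstrap 95% interval over genes -0.37 to -0.09). A smaller thalamic share cannot be told apart from other causes. The group difference of the markers' mean log2 CPM per library was -0.17 ± 0.07 SE, and -0.27 ± 0.19 SE with the score, within 2 SE of 0. The slope of this mean on the score was -0.08 ± 0.14 SE, so no fall of the markers with a lower score was seen. The score correlated with the group at -0.91, which widens these errors, and the markers vary together between libraries. These values therefore cannot decide. An effect of the genotype on single myelin genes stays open.

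Gm15446 and Zfp932, neighbours on chromosome 5, were both lower in NS-DADm mice. Their summed counts had a log2 fold change of -0.81 ± 0.07 SE (64.2 ± 5.9 to 36.7 ± 1.0 CPM). The sum had to be lower, because both genes had already been seen to be lower, so it is not a separate test. Reads only moving from one copy to the other would not lower both. The sum does not address reads of either copy that were left out as not unique. An effect of the genotype on both genes, or a strain difference between the groups, stays open. Nnt, in which a common C57BL/6 substrain carries a deletion, was higher in NS-DADm mice (19.8 to 29.5 CPM in WT, 40.5 to 42.7 CPM in NS-DADm), and the gene counts do not show which exons were read.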
